A study of Homo sapiens with 6 samples.

How the data were processed

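Human fetal lung fibroblasts of the line IMR-90 were cultured without (3 arrays) or with TGF-β1 at 2 ng/ml (3 arrays), and biotin-labelled RNA was hybridised to Affymetrix U133A arrays, per the labels. The deposited values are linear array signals in units of intensity, made with MAS5 per the submitters' processing notes, its version and settings not given in the sources used here. The values were checked and found to be brought to a common distribution in the deposited table. The 2% trimmed means of the 6 arrays ran from 1046.72 to 1047.35, a ratio of 1.0006, and 4.73 to 4.89% of each array's values lay below 0. Plain MAS5 signals are positive and not of equal distribution, so a step that the notes do not name also shaped the deposited values, and what a value below 0 stands for is unknown. Because the deposited distributions were already equal, alternatives that rescale whole arrays tested nothing about scaling. Group and replicate were taken from the sample titles. The series design text gives 48 hours and the treatment protocol 18 hours after treatment, and the time was not used. The series design text also gives the arrays codes (C0, C2 and C3, and T0, T5 and T7) that it does not link to the replicate numbers, and the numbers were not used to pair samples.

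Of 22283 probe sets, 68 array controls were left out of the tests. The gene table (human reference genes, names only, so no positions are given) named 1 gene for 19065 of the other 22215 probe sets, several for 1043 and none for 2107. Values below 0 were set to 0, the 25th percentile of all values (131) was added, and log2 was taken. The 25% of probe sets with the lowest mean log2 value were left out, which left 16661 tested. A gene was read at its probe set with the highest mean log2 value among the 14613 tested with 1 symbol, giving 9717 genes. Where a named gene has several probe sets tested of which some were not called, their number and the number called are stated, with the mean of its probe sets where that ended the call.

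Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), two-sided, with the group as the only term, and p-values were adjusted by Benjamini-Hochberg over all probe sets tested at a threshold of 0.05. A change of at least 2-fold meant an absolute log2 difference of 1 or more. The median residual SD was 0.212, with 4 residual and 3.952 prior degrees of freedom. The share of genes that rose has an exact (Clopper-Pearson) interval. There were 33 gene lists with 723 distinct genes, of which 72 had no probe set naming them alone and 578 were tested. Lists with at least 5 genes tested were compared with all other genes by camera (preset correlation 0.01, Benjamini-Hochberg over 32 lists), with camera's estimated correlation and fry beside it. For each list the members called over all probe sets and those adjusted over the list alone were counted. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

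The naming rule took the 10 genes with the largest rise and the 10 with the largest fall among those called with non-overlapping groups, 8 genes fixed by name, and up to 4 of the largest called members of each list (or up to 2 where none was called). It gave 121 genes, of which 113 were called, 92 of these in every fit without 1 array. From each list the text gives mainly those that passed in every such fit, a choice made after the values were seen, and the others with the arrays their call depends on. A list's members that moved against the rest are also named.

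The comparison, model, lists, naming rule and the following alternative settings were fixed before the data were examined. These were pseudocounts of 1, of the 10th percentile (35) and of the 50th percentile (412), quantile normalization, centring on array medians, no filter and a filter on the dimmer 50% of probe sets, eBayes without a trend and with robust fitting, array weights, the replicate number as a block, leaving out each array, the mean of a gene's probe sets, and the estimated correlation. After the data were seen, a block for the split of the arrays by the 5′/3′ ratio of the array's long human control transcript was added, and a fit without control 1 and TGF-β1 2. The 10 splits of the 6 arrays into 3 and 3 were each fitted in the same way. Gene families sharing a name stem (333 with the aminoacyl-tRNA synthetases) were screened with camera, also after the data were seen.

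The procedure was tested on simulated data with 16661 probe sets, 50 changed at each size. It recovered 4 of 50 at a true log2 difference of 0.5, 36 at 1, 50 at 2 and 50 at 3, and 10 unchanged probe sets stood among 150 called. The shifted list was called and 0 of 31 unshifted lists were. The noise was drawn independently for each probe set and array. The simulation therefore says nothing on false calls among correlated genes or arrays, and estimated correlations within the real lists reached 0.472.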

Results

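IMR-90, an established line of human fetal lung fibroblasts (mesenchymal cells), was grown with or without transforming growth factor β1 (TGF-β1) at 2 ng/ml, and total RNA was hybridised to Affymetrix U133A arrays. There were 3 arrays of untreated control cells and 3 arrays of TGF-β1-treated cells, whose titles call them biological replicates. The labels give both 48 hours and 18 hours as the time of RNA collection after treatment, so the time is uncertain. The deposited table held 22283 probe sets, of which 16661 were tested. These measured 9717 genes, each read at its brightest probe set. Levels below are array intensities, given as mean ± SD with n = 3 in each group, and differences are of log2(intensity + 131), which understates the change of genes at low levels. The number of arrays limits the precision of every value, and nothing in the labels says whether the replicates were separate cultures or days, so the p-values measure only the spread between these 6 samples.

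The comparison asked which transcripts TGF-β1, a growth factor known to drive fibroblasts toward contractile, matrix-producing myofibroblasts, changed in these cells. NOX4, an NADPH oxidase that makes hydrogen peroxide, rose from 251.3 ± 37.5 in control cells to 5367 ± 374 with TGF-β1. ACTA2, smooth muscle α-actin, rose from 5656 ± 716 to 39150 ± 3210, and COMP, a cartilage matrix protein, rose from −28.33 ± 53.3 to 2708 ± 225. Genes for collagen assembly, contractile filaments, endoplasmic reticulum chaperones, amino acid supply and cholesterol synthesis were higher as groups and lung mesenchymal transcription factors lower (camera with a preset correlation between genes, a result that no group kept with an estimated correlation). TRPA1, a cation channel, fell from 4304 ± 596 to 207 ± 45.9.

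With limma, 2507 of the 16661 probe sets changed (15.05%) at a Benjamini-Hochberg threshold of 0.05, of which 1252 rose and 1255 fell, and 5058 had an unadjusted p under 0.05. At least 2-fold changes numbered 983, of which 566 rose and 417 fell, or 613 with a pseudocount of 412 in place of 131. With array weights, which were lowest in control 1 (0.358) and TGF-β1 2 (0.371), 7127 probe sets and 4154 genes were called. Counted by gene, 1604 of 9717 changed (16.51%), 754 up and 850 down, and 595 of these changed at least 2-fold, 325 up and 270 down. The arrays had been brought to a common distribution, so a net shift of all genes in the same direction would not show in the counts up and down. The share that rose was 47.01% (exact 95% interval 44.54 to 49.48, for counting error only, as genes are not independent). It crossed 50% when 1 array was left out, at 54.14% without control 2, 55.42% without control 3, 54.66% without TGF-β1 1 and 54.3% without TGF-β1 3. Every TGF-β1 array lay above, or every one below, every control array in 3501 genes (36.03%), where chance gives 10%. An exact two-sided test of 1 gene in 3 against 3 arrays cannot give a p under 0.1. The number of genes called fell to 761 without control 2, 637 without control 3, 644 without TGF-β1 1 and 639 without TGF-β1 3, and was 2034 without control 1 and 2124 without TGF-β1 2. The corresponding probe set counts without control 2, control 3, TGF-β1 1 and TGF-β1 3 were 1216, 1018, 1026 and 1007.

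With the pseudocount of 131 IGFBP3, a carrier of insulin-like growth factors, had the largest log2 difference, a rise by 4.90 (SE 0.66, adjusted p = 0.00309), from 917 ± 1060 to 24600 ± 11100. IL11, a cytokine of the interleukin-6 family, rose by 4.81 (adjusted p = 0.00336) to 13620 ± 9350, and COMP by 4.40 (adjusted p = 2e-05). Within each group IGFBP3 and IL11 also read highest in the arrays with a high 5′/3′ ratio described below. IGFBP3 read 2141 in control 1 against 291 and 319 in the other controls, and 11767 in TGF-β1 2 against 30644 and 31389. IL11 read 2824 in TGF-β1 2 against 18978 and 19045 in the other TGF-β1 arrays. The rank depends on the pseudocount, since COMP had 6.16 and IGFBP3 5.16 with a pseudocount of 35, and 2.91 and 4.39 with 412. With a pseudocount of 1 the filter on dim probe sets left COMP out, so it was not tested there. IL11 stood at 2.69 (adjusted p = 0.0175) with a pseudocount of 1, where its other probe set was the one read, and at 3.64 for the mean of its 2 probe sets. ADAM12, a membrane metalloprotease, rose by 4.02 (adjusted p = 0.000429), with 3 of its 4 probe sets called. NOX4 rose by 3.85 (SE 0.143, adjusted p = 2.01e-05), its control arrays reading 213 to 288 and its TGF-β1 arrays 5142 to 5799. Next came MGP, an inhibitor of calcification, at 3.63, PLN, a regulator of the muscle calcium pump, at 3.57, INHBA, which encodes the activin A subunit, at 3.54, CNN1 (calponin) at 3.47 and SLC7A5, a transporter of large neutral amino acids, at 3.44. All 10 had every TGF-β1 array above every control array, as the naming rule required.

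With the same pseudocount TRPA1 had the lowest log2 difference, −3.71 (adjusted p = 3.6e-05), at 1 of its 2 probe sets. ADH1B, an alcohol dehydrogenase, fell from 1362 ± 654 to −58 ± 46.3 (log2 difference −3.42, adjusted p = 5e-04), and BMP4, a bone morphogenetic protein, from 786 ± 244 to −115.7 ± 86.8 (log2 difference −2.77). ALDH1A3, which makes retinoic acid, fell from 1620 ± 1460 to −0.667 ± 81.7 (log2 difference −3.18, adjusted p = 0.00557). The differences of these genes are limited by the pseudocount, and with 35 in its place ADH1B (−5.21), ALDH1A3 (−4.53) and BMP4 (−4.50) lay below TRPA1 (−4.17). With a pseudocount of 1 the filter on dim probe sets left out ADH1B, ALDH1A3, BMP4 and SELENOP, so they were not tested there. NPTX1 fell from 4714 ± 1380 to 394.7 ± 34.8, PDGFD, a platelet-derived growth factor, from 5929 ± 1580 to 719.7 ± 290, and PLAT, tissue plasminogen activator, from 10180 ± 1510 to 1489 ± 626. SOCS1, an inhibitor of cytokine signalling, fell by 2.72 on the log2 scale at 2 of its 3 probe sets called, and TMEM35A fell by 2.71. SELENOP, a selenium carrier, had a log2 difference of −3.29 (adjusted p = 0.0112), which did not pass without control 3 (0.0517), TGF-β1 1 (0.0609) or TGF-β1 3 (0.0558). SELENOP was also lower, by 1.78 with the group in the fit (adjusted p = 4.3e-05), in the arrays with a high 5′/3′ ratio described below. All 10 had every TGF-β1 array below every control array, as the naming rule required.

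**Figure D1:**
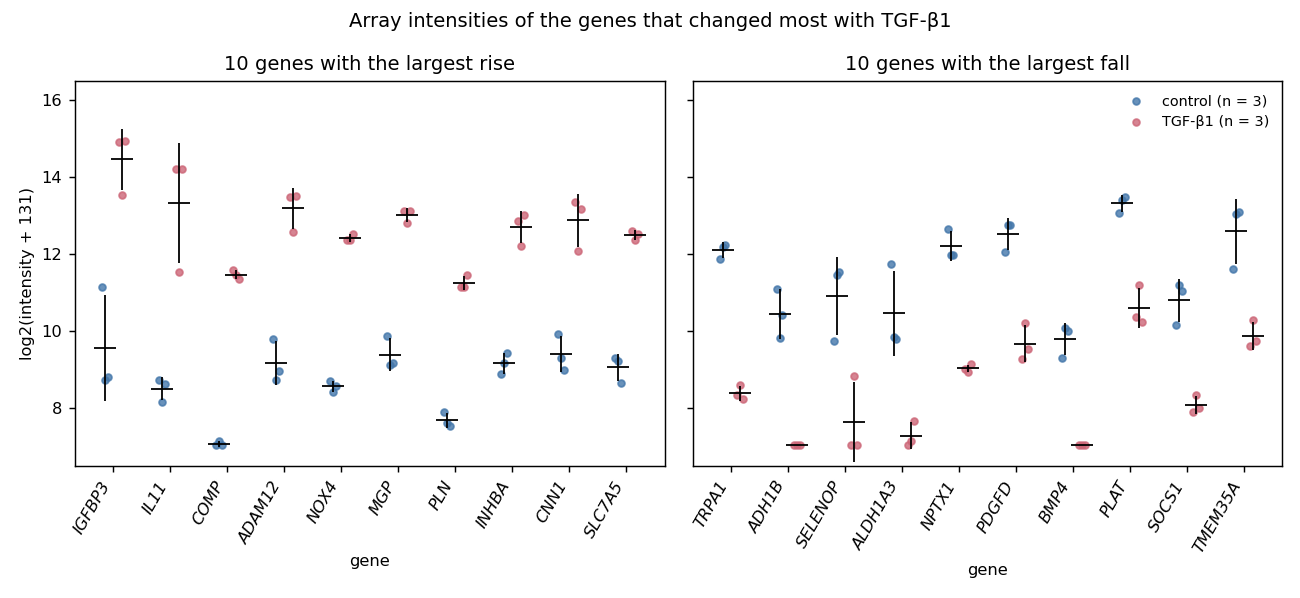
Array intensity as log2(intensity + 131), with values below 0 set to 0, of the 10 genes with the largest rise and the 10 with the largest fall, 1 point per array (3 control, 3 TGF-β1), horizontal marks for means and bars for the SD of the log2 values. No TGF-β1 point overlaps the control points of its gene, since the genes were chosen among those with non-overlapping groups.

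Of the genes named in advance, SMAD7, an inhibitor of TGF-β signalling, rose from 517.7 ± 75.1 to 2080 ± 250 (log2 difference 1.77, adjusted p = 0.000599). TAGLN, a smooth muscle actin-binding protein, rose from 5633 ± 4390 to 31610 ± 4980 (2.70, adjusted p = 0.00631), and ACTA2 rose by 2.77 (adjusted p = 2.49e-05). COL1A1, a chain of type I collagen, rose from 37910 ± 1190 to 51310 ± 3700 (0.43, adjusted p = 0.00479) at 2 of its 4 probe sets called, and the call was lost when the variance was fitted without a trend (adjusted p = 0.0611). In these 4 genes every TGF-β1 array lay above every control array. FN1, fibronectin, stood at 41920 ± 1490 and 43560 ± 1740 (0.06, adjusted p = 0.564), none of its 6 probe sets passing (0.64 for the mean of all 6, adjusted p = 0.213). FN1 and, with TGF-β1, COL1A1 at up to 55555 lay close to the arrays' maxima of 54576 to 61682. CCN2, a matricellular growth factor, stood at 14380 ± 7860 and 27180 ± 6700 (1.01, SE 0.342, adjusted p = 0.0881) with overlapping groups, but passed without control 1 (0.00318) or without TGF-β1 2 (0.0496), and with array weights (1.42, adjusted p = 0.000545). With the 5′/3′ split described next as a block its log2 difference was 0.69 (adjusted p = 0.00138). The remaining 1 of the 8 genes named in advance was not analysed here, since the gene table names no probe set for it alone.

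The arrays also differed within each group. On the first principal component (65.35% of the variance) the control arrays lay at −13.02, −49.98 and −43.08 and the TGF-β1 arrays at 49.49, 9.08 and 47.5, so that control 1 and TGF-β1 2 stood nearest to the other group. On the array's long human control transcript, the 5′ signal as a percentage of the 3′ signal, a sign of RNA or labelling quality, was 19.36 in control 1, 17.36 in TGF-β1 1 and 27.85 in TGF-β1 3, against 1.154 in control 2, 3.684 in control 3 and 2.826 in TGF-β1 2. The 3′ over 5′ ratios of the abundant GAPDH and beta-actin controls stayed near 1 in all 6 arrays, at 0.830 to 0.982 and 0.856 to 1.24, though in both every low-ratio array lay above every high-ratio array. This split into high-ratio and low-ratio arrays cuts across the treatment, and 2944 probe sets differed by it with the group in the fit, 1369 higher and 1575 lower in high-ratio arrays. With the split as a block, 4323 probe sets and 2648 genes differed between the groups, among them every one of the 1604 genes called without the block. NOX4 differed by 3.74 within the high-ratio arrays (1 control, 2 TGF-β1) and by 3.86 within the low-ratio arrays (2 control, 1 TGF-β1), each value resting on a group of 1 array. Without control 1 and TGF-β1 2, 6773 probe sets and 3910 genes were called, but that fit sets low-ratio controls against high-ratio TGF-β1 arrays, so that its differences hold those of the split as well as those of the treatment. The fits without control 1 or without TGF-β1 2 alone, and the array weights, lean the same way in part, and calls gained in them cannot be put down to the treatment alone.

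**Figure D2:**
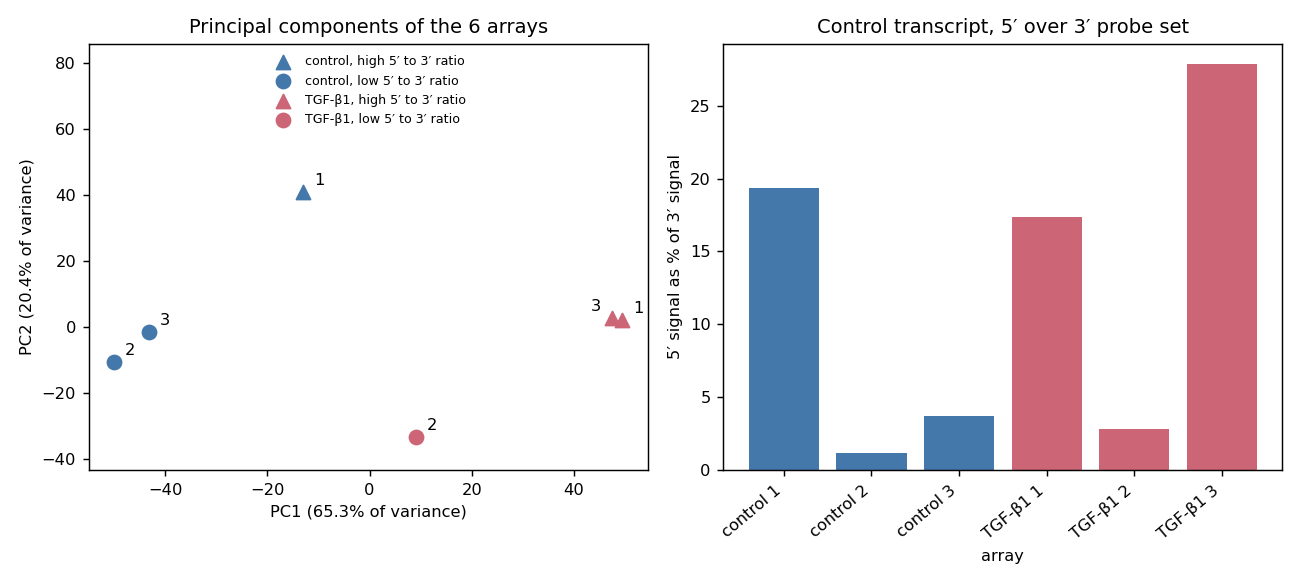
Left, the 6 arrays on the first and second principal components of the tested probe sets (numbers are replicate numbers, colours the groups, shapes the 5′/3′ ratio), and right, the 5′ signal of the array's long human control transcript as a percentage of its 3′ signal, per array. Control 1 and TGF-β1 2 lie nearest to the other group on the first component, and the ratio is 17.36 or more in 3 arrays and 3.684 or less in the other 3.

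Among the 578 genes of the 33 gene lists that were tested, 243 changed, and 134 of these passed in every fit without 1 array while 109 did not pass without at least 1 array. The 243 all kept their sign in those fits, which leaving out 1 array cannot change in a gene whose groups do not overlap. Of 32 lists large enough for camera, limma's test of a set against all other genes, 15 were called, 11 higher and 4 lower with TGF-β1. With an estimated correlation between genes camera called 0, and 6 lists had an unadjusted p under 0.05. Adjusted p-values of lists under other settings are those of the preset correlation. By fry, which tests whether a set's genes move one way on balance, 23 lists were called, and 31 by its test of change in either direction. Members named below as changed had every TGF-β1 array on 1 side of every control array, and members outside the naming rule were chosen after their values were seen. A member counted as not passing was read at its brightest probe set only. For some of these the mean of the gene's probe sets passed, among them GSTM4 (−0.87, adjusted p = 0.00866), BGN (0.91, adjusted p = 0.0179) and SCD (1.05, adjusted p = 0.0232).

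**Figure D3:**
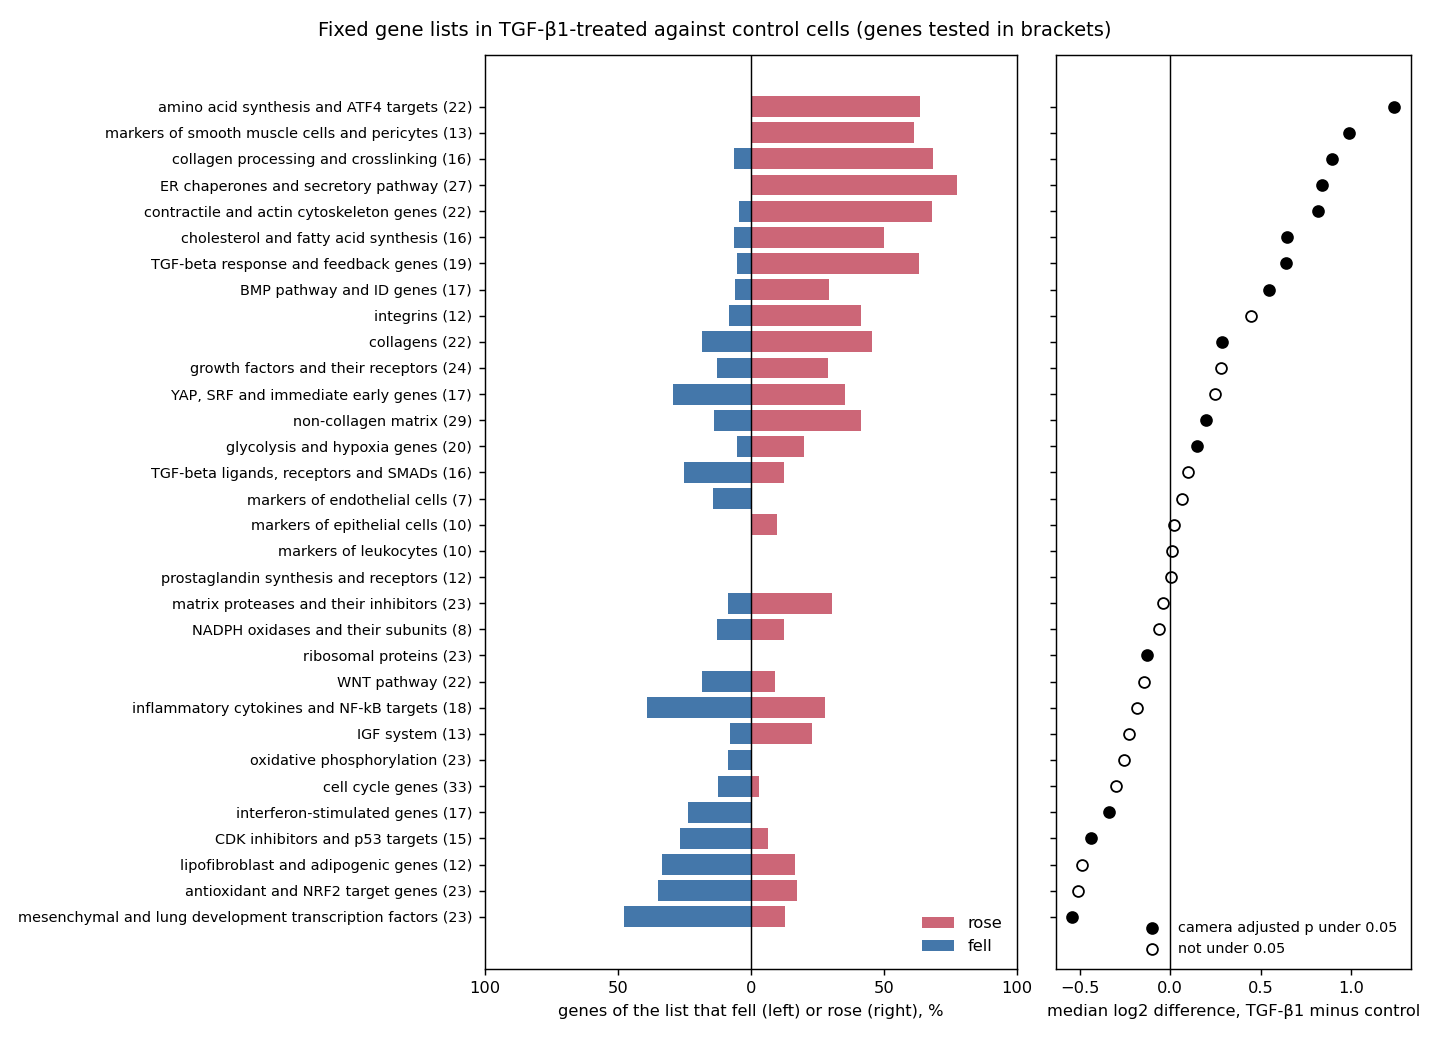
The 32 lists with at least 5 genes tested, with the percentage of each list's genes that fell or rose (left) and the list's median log2 difference, TGF-β1 minus control (right, filled where camera's adjusted p was under 0.05). The median ran from −0.54 in mesenchymal and lung development transcription factors to 1.24 in amino acid synthesis and ATF4 targets.

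Of 19 TGF-β response and feedback genes, 12 rose, 1 fell and 6 did not pass (14 and 1 adjusted over the list alone), with a median log2 difference of 0.64. The list was higher by camera (adjusted p = 9.06e-07, and adjusted p = 0.068 with an estimated correlation), and 6 of the 13 calls held without any 1 array. PMEPA1, a feedback inhibitor of the pathway, rose by 2.86, GADD45B, a stress-response gene, by 2.74, NEDD9, a focal adhesion scaffold, by 1.89 and SKIL, a SMAD co-repressor, by 1.76. BHLHE40, a transcriptional repressor, rose by 1.94 but did not pass without TGF-β1 1 (0.0726) or TGF-β1 3 (0.0775). TSC22D1 fell by 0.38 (adjusted p = 0.0384), a call lost without control 1 (0.0581), control 2 (0.123), control 3 (0.107), TGF-β1 1 (0.139) or TGF-β1 3 (0.119). In the list of TGF-β ligands, receptors and SMADs, 2 of 16 genes rose, 4 fell and 10 did not pass (3 and 4 adjusted over the list alone). Camera did not call it (adjusted p = 0.968), its median (0.10) and test pointing up and its mean (−0.07) down. The receptor-activated SMAD3 fell from 3590 ± 379 to 546.7 ± 203 (log2 difference −2.49) at 3 of its 4 probe sets called, the coreceptor TGFBR3 by 2.08 and the receptor TGFBR2 by 1.27 at 1 of its 2 probe sets, the mean of which gave −0.67 (adjusted p = 0.363). TGFB1 itself rose from 3104 ± 873 to 8374 ± 1580 (1.42). LTBP1 (0.60) and LTBP4 (−0.91), which bind latent TGF-β, passed with all arrays but not without control 2 (adjusted p 0.114 and 0.0985), control 3 (0.13 and 0.092), TGF-β1 1 (0.0921 and 0.0681) or TGF-β1 3 (0.0678 and 0.113), nor LTBP1 without TGF-β1 2 (0.0511). LTBP1 was called at 1 of its 2 probe sets and LTBP4 at 1 of 3.

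Among 17 genes of the BMP pathway and ID genes, 5 rose, 1 fell and 11 did not pass (5 and 2 adjusted over the list alone). The median was 0.54 and camera called the list (adjusted p = 0.0252, and adjusted p = 0.245 with an estimated correlation), but not without control 1 (0.0655). INHBA rose by 3.54 and the transcriptional inhibitor ID3 by 1.59, while BMP4 fell by 2.77. The receptor BMPR2 rose by 1.07 but did not pass without control 3 (0.0501). ID2 (0.83, at 1 of its 2 probe sets) and ID4 (0.64) did not pass without control 2 (0.0595 and 0.135), control 3 (0.0645 and 0.0919), TGF-β1 1 (0.0846 and 0.112) or TGF-β1 3 (0.0664 and 0.108).

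The contractile and actin cytoskeleton genes rose in 15 of 22 cases, 1 fell and 6 did not pass (16 and 1 adjusted over the list alone), with a median of 0.82. Camera gave an adjusted p = 1.31e-10, and an adjusted p = 0.068 with an estimated correlation, and 11 of the 16 calls held without any 1 array. CNN1 rose by 3.47, ACTG2, smooth muscle γ-actin, from 2633 ± 669 to 19350 ± 3040 (2.83) and TPM1, a tropomyosin, by 2.31. The muscle actins resemble each other closely, so how far their probe sets tell them apart is uncertain. LPP, a focal adhesion protein, fell by 0.52 at its brightest probe set while its 2 others rose (0.26 for the mean of all 3, adjusted p = 0.16). The fall did not pass without control 2 (0.104), control 3 (0.0938), TGF-β1 1 (0.101) or TGF-β1 3 (0.111). Markers of smooth muscle cells and pericytes, many of them contractile genes shared with that list, rose in 8 of 13 cases, none fell and 5 did not pass (9 and 0 adjusted over the list alone). Their median was 0.99 (camera adjusted p = 2.67e-07, and adjusted p = 0.068 with an estimated correlation), with PLN at 3.57, LMOD1, an actin nucleator, at 2.23 and MYH11, smooth muscle myosin, at 1.46.

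Of 22 collagens, 10 rose, 4 fell and 8 did not pass (11 and 6 adjusted over the list alone), and camera called the list higher (median 0.28, adjusted p = 0.00833, and adjusted p = 0.245 with an estimated correlation). Its median was 0.55 without control 1 and 0.58 without TGF-β1 2. COL4A1, a basement membrane collagen, rose from 4358 ± 832 to 19440 ± 1000 (2.14), COL8A1 by 2.09 and COL5A1 by 1.87. COL21A1 fell by 2.33. The falls of COL14A1 (−1.56), COL13A1 (−1.19) and COL6A1 (−0.43) did not hold without every array. COL14A1 did not pass without control 2 (0.11), control 3 (0.127), TGF-β1 1 (0.127) or TGF-β1 3 (0.119), COL13A1 without TGF-β1 1 (0.0517) and COL6A1 without control 2 (0.0567) or TGF-β1 3 (0.0676). COL14A1 was called at 1 of 3 probe sets, COL13A1 at 1 of 3 (−0.59 for their mean, adjusted p = 0.264) and COL6A1 at 1 of 5 (−0.50, adjusted p = 0.259).

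Collagen processing and crosslinking genes rose in 11 of 16 cases, 1 fell and 4 did not pass (11 and 2 adjusted over the list alone). The list was higher (median 0.89, camera adjusted p = 1.71e-06, and adjusted p = 0.245 with an estimated correlation), and 6 of its 12 calls held without any 1 array. LOX, which crosslinks collagen, rose by 1.45 at 1 of its 3 probe sets (adjusted p = 0.0507 for their mean), SERPINH1, a collagen chaperone, from 8520 ± 2540 to 20690 ± 1370 (1.30) and PLOD2, a lysyl hydroxylase, by 1.29. P3H1, a prolyl hydroxylase, rose by 1.30 and PCOLCE, an enhancer of procollagen cleavage, fell by 0.40, but they did not pass without control 2 (0.0891 and 0.0983), control 3 (0.106 and 0.106), TGF-β1 1 (0.117 and 0.0961) or TGF-β1 3 (0.111 and 0.106). This list also moved with the 5′/3′ split, 7 of its genes being higher and 0 lower in high-ratio arrays (median 0.31), and with the split as a block its median between the groups was 0.77.

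Of 29 non-collagen matrix genes, 12 rose, 4 fell and 13 did not pass (13 and 7 adjusted over the list alone). Camera called the list higher (median 0.20, adjusted p = 0.0246, and adjusted p = 0.534 with an estimated correlation). It did not do so with a pseudocount of 1 (0.0671), with the dimmer 50% of probe sets left out (0.054) or with the 5′/3′ split as a block (median 0.05, adjusted p = 0.0626), and 11 of its genes were higher and 0 lower in high-ratio arrays. The median ranged from 0.08 without TGF-β1 1, 0.10 without control 2 and 0.12 without control 3 to 0.32 without TGF-β1 2 and 0.39 without control 1. COMP rose by 4.40, ELN, elastin, from 836 to 6800 (2.77), TNC, tenascin C, from 8264 ± 983 to 26910 ± 383 (1.69) and FBLN5, an elastic fibre protein, by 1.63. Those that fell were LAMA4 (−1.61), NID2 (−1.33), LAMB1 (−1.21) and NID1 (−0.89), while LAMC1, a laminin like LAMA4 and LAMB1, did not pass (−0.18, adjusted p = 0.286). NID1 did not pass without control 3 (0.0659) or TGF-β1 1 (0.0618). LAMA4 was called at 1 of its 4 probe sets (−0.84 for their mean, adjusted p = 0.0846) and NID1 at 1 of 2 (−0.53, adjusted p = 0.118).

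Matrix proteases and their inhibitors rose in 7 of 23 cases, 2 fell and 14 did not pass (7 and 3 adjusted over the list alone). Camera did not call the list (adjusted p = 0.286), its median (−0.04) lying below and its mean (0.11) and test above 0. ADAM12 rose by 4.02, ADAM19 by 2.11 at 1 of its 2 probe sets and SERPINE2, a protease inhibitor, from 6694 ± 951 to 28440 ± 495 (2.07). PLAT fell by 2.73, and PLAU, urokinase, by 1.30, though not without control 3 (0.0646), TGF-β1 1 (0.0751) or TGF-β1 3 (0.0686). Integrins rose in 5 of 12 cases, 1 fell and 6 did not pass (5 and 3 adjusted over the list alone), with a median of 0.45 and a camera adjusted p = 0.0642. That list was called without control 3 (0.046), with the dimmer 50% of probe sets left out (0.0117) and with the split as a block (0.0466). ITGA7 rose by 1.34, ITGA5 by 1.24 and ITGAV by 1.05. Without control 2, control 3, TGF-β1 1 or TGF-β1 3, respectively, the calls of ITGB3 (1.22, adjusted p 0.146, 0.163, 0.173 and 0.171), ITGA3 (0.70, adjusted p 0.0712, 0.136, 0.122 and 0.122) and ITGA10 (−0.67, adjusted p 0.0863, 0.098, 0.0775 and 0.0995) were lost. ITGB3 was called at 1 of its 5 probe sets (0.56 for their mean, adjusted p = 0.107).

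NOX4 was the single riser among 8 NADPH oxidases and subunits, 1 fell and 6 did not pass (1 and 1 adjusted over the list alone). The median (−0.06) lay below 0 and the mean (0.23) and test above it (camera adjusted p = 0.972). RAC2, a small GTPase that activates the phagocyte oxidase, fell from 1996 to 547 (log2 difference −1.66). Among 23 antioxidant and NRF2 target genes, 4 rose, 8 fell and 11 did not pass (5 and 12 adjusted over the list alone), and 3 of the 12 calls held without any 1 array. The list, with a median of −0.51, was not called (camera adjusted p = 0.0512) but was called without control 2 (0.0427), TGF-β1 2 (0.0158) or TGF-β1 3 (0.0436), with quantile normalization (0.0449), array weights (0.0283), the mean of each gene's probe sets (0.0372) or the split as a block (0.0345). GCLC, the catalytic subunit of glutathione synthesis, fell from 2110 ± 220 to 707.7 ± 169 (−1.44) and CAT, catalase, from 3725 ± 506 to 1306 ± 257 (−1.43) at 1 of its 2 probe sets. GPX1, a glutathione peroxidase, had a difference of −1.07 that did not pass without control 2 (0.0922), control 3 (0.108), TGF-β1 1 (0.118) or TGF-β1 3 (0.109). PRDX6, a peroxiredoxin, rose by 0.66. The rises of GCLM (1.19), PRDX4 (0.43) and PRDX1 (0.36) were lost without control 2 (0.129, 0.0741 and 0.16), control 3 (0.152, 0.0827 and 0.167), TGF-β1 1 (0.123, 0.059 and 0.105) or TGF-β1 3 (0.141, 0.0884 and 0.161), and those of GCLM and PRDX1 without TGF-β1 2 (0.0626 and 0.0703).

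Inflammatory cytokines and NF-κB targets went both ways, 5 of 18 rising, 7 falling and 6 not passing (5 and 8 adjusted over the list alone). Camera did not call the list (adjusted p = 0.78), its median (−0.18) and test pointing down and its mean (0.09) up. IL11 rose by 4.81, TNFAIP6, a hyaluronan-binding protein, by 2.70 and the cytokine LIF by 2.20, and VCAM1, an adhesion molecule, fell from 2234 ± 120 to 250.3 ± 139 (log2 difference −2.69). IL1R1 (−1.76) and CXCL12 (−1.59), each called at 1 of its 2 probe sets, also fell and passed in every fit without 1 array. IL6 (0.85) and IL7R (0.72) passed with all arrays but not without control 2 (0.0609 and 0.106), control 3 (0.0715 and 0.125), TGF-β1 1 (0.063 and 0.0944) or TGF-β1 3 (0.0623 and 0.116). Of 17 interferon-stimulated genes none rose, 4 fell and 13 did not pass (0 and 7 adjusted over the list alone). The list was lower by camera (median −0.34, adjusted p = 0.00938, and adjusted p = 0.24 with an estimated correlation), but not with the dimmer 50% of probe sets left out (0.27). IFITM1, an antiviral membrane protein, fell from 4359 ± 343 to 2152 ± 468 (−0.99). IFIT1 (−2.30), IFIT3 (−0.94) and IFI44 (−0.65, at 1 of its 2 probe sets) did not pass without control 2 (0.0553, 0.0671 and 0.0977), control 3 (0.0674, 0.0858 and 0.135), TGF-β1 1 (0.0758, 0.0685 and 0.106) or TGF-β1 3 (0.0719, 0.0621 and 0.11). No gene of prostaglandin synthesis and receptors passed (0 of 12, and 0 adjusted over the list alone, with 2 at an unadjusted limma p under 0.05, median 0.01, camera adjusted p = 0.817). The largest difference there was in PTGDS, a prostaglandin D synthase, at 12800 ± 9900 and 4070 ± 5320 (−1.78, adjusted p = 0.344), which passed without control 1 (−2.98, adjusted p = 0.0455) and with array weights (−3.40, adjusted p = 0.00302). PTGDS also followed the 5′/3′ split, at −3.40 in high-ratio against low-ratio arrays, and with the split as a block it differed between the groups by −0.65 (adjusted p = 0.00192). PTGS1, a cyclooxygenase, stood at 1232 ± 521 and 4562 ± 2730 (1.59, adjusted p = 0.0857) and passed without control 1 (0.0487) or TGF-β1 2 (0.00283), with array weights (0.000533) and with the split as a block (1.10, adjusted p = 0.00252).

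Cell cycle genes were called in 5 of 33 cases, 1 up and 4 down, and 28 did not pass (1 and 4 adjusted over the list alone), with a median of −0.30 (camera adjusted p = 0.0512). They moved with the 5′/3′ split, 16 being higher and 0 lower in high-ratio arrays (median 0.48). With the split as a block 1 rose and 17 fell between the groups (median −0.41, adjusted p = 5.61e-05 with the preset correlation). With an estimated correlation the list had an adjusted p = 0.718 over all arrays, without the block. Within the high-ratio and the low-ratio arrays the medians were −0.53 and −0.38. Without control 1 and TGF-β1 2 together, where the split and the treatment coincide, 8 rose and 5 fell (median 0.15, adjusted p = 0.445), and without control 1 alone the median was −0.01. The list was called lower without control 2 (0.00818), control 3 (0.00617), TGF-β1 1 (0.0197) or TGF-β1 3 (0.00999) and with the mean of each gene's probe sets (0.0299). TYMS, thymidylate synthase, fell from 3162 ± 315 to 1346 ± 97 (−1.16), and CENPF, a kinetochore protein, by 1.17 at 1 of its 2 probe sets. The DNA replication helicase genes MCM7 (−0.89) and MCM4 (−0.67) and the cyclin CCNA2 (0.65) did not pass without control 2 (0.0543, 0.0872 and 0.164), TGF-β1 1 (0.0625, 0.104 and 0.148) or TGF-β1 3 (0.0691, 0.115 and 0.159), nor MCM4 and CCNA2 without control 3 (0.12 and 0.168). MCM7 was called at 1 of its 2 probe sets, MCM4 at 1 of 3 (−0.23 for their mean, adjusted p = 0.447) and CCNA2 at 1 of 2 (0.78, adjusted p = 0.0768). Of 15 CDK inhibitors and p53 targets, 1 rose, 4 fell and 10 did not pass (1 and 6 adjusted over the list alone), and the list was lower (median −0.44, camera adjusted p = 0.00945, and adjusted p = 0.291 with an estimated correlation). CDKN2B, the inhibitor p15, rose from 10 ± 21.9 to 397.7 ± 187 (1.79), and CDKN1C fell by 1.35, CCNG1, a cyclin induced by p53, by 1.14 and CDKN1B by 0.74. XPC, a DNA repair gene, had a difference of −0.69 that did not pass without control 2 (0.121), control 3 (0.141), TGF-β1 1 (0.124) or TGF-β1 3 (0.117).

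Glycolysis and hypoxia genes rose in 4 of 20 cases, 1 fell and 15 did not pass (5 and 1 adjusted over the list alone). Camera called the list higher (median 0.15, adjusted p = 0.0314, and adjusted p = 0.24 with an estimated correlation), but not without control 1 (0.153) or with array weights (0.0548). PFKP, a phosphofructokinase, rose from 2377 to 7685 (1.63) and LDHA, lactate dehydrogenase, from 9498 ± 920 to 21970 ± 2620, while ADM, adrenomedullin, fell from 5573 to 1944 (−1.44). VEGFA (0.82), a vascular growth factor, and the glucose transporter SLC2A1 (0.81) did not pass without control 2 (0.112 and 0.118), control 3 (0.111 and 0.153), TGF-β1 1 (0.134 and 0.151) or TGF-β1 3 (0.134 and 0.152). VEGFA was called at 2 of its 4 probe sets (0.95 for their mean, adjusted p = 0.0506) and SLC2A1 at 1 of 2 (0.43, adjusted p = 0.147). Of 23 oxidative phosphorylation genes none rose, 2 fell and 21 did not pass (0 and 2 adjusted over the list alone, median −0.26, camera adjusted p = 0.0714). This list was called lower without TGF-β1 2 (0.0176), with no filter on dim probe sets (0.046) and with array weights (0.027), and it was also lower in high-ratio arrays (median −0.18). NDUFB5 (−0.57) and COX6C (−0.52), subunits of respiratory complexes, did not pass without control 2 (0.0909 and 0.0535), control 3 (0.111 and 0.0651), TGF-β1 1 (0.105 and 0.0534) or TGF-β1 3 (0.11 and 0.0599).

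Cholesterol and fatty acid synthesis genes rose in 8 of 16 cases, 1 fell and 7 did not pass (9 and 1 adjusted over the list alone). The list was higher (median 0.65, camera adjusted p = 1.46e-05, and adjusted p = 0.24 with an estimated correlation). MSMO1 and SQLE, enzymes of sterol synthesis, rose by 1.14 and 1.09, and ACLY, which makes acetyl-CoA from citrate, from 6190 ± 544 to 13140 ± 275 (1.07). INSIG1, a regulator of the pathway, rose by 1.24 but did not pass without TGF-β1 1 (0.0543) or TGF-β1 3 (0.061). LSS, lanosterol synthase, fell by 0.96 at 2 of its 3 probe sets but did not pass without control 3 (0.0585), TGF-β1 1 (0.057) or TGF-β1 3 (0.0563).

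Amino acid synthesis genes and targets of the transcription factor ATF4 rose in 14 of 22 cases, none fell and 8 did not pass (18 and 1 adjusted over the list alone). The median of 1.24 was the highest of the 32 lists tested (camera adjusted p = 3.1e-09, and adjusted p = 0.24 with an estimated correlation), and 6 of the 14 calls held without any 1 array. SLC7A5 rose from 414.3 ± 121 to 5688 ± 493, CHAC1, which degrades glutathione, by 2.34 and TRIB3, a pseudokinase, by 1.47. ASNS, asparagine synthetase, rose from 1309 ± 1250 to 7512 ± 2290 (2.69) and PSAT1, of serine synthesis, by 2.65, but they did not pass without control 3 (0.0558 and 0.0715), TGF-β1 1 (0.0709 and 0.0823) or TGF-β1 3 (0.0631 and 0.0783). In the 5′/3′ split, 13 of the genes were higher and 1 lower in high-ratio arrays (median 0.45). With the split as a block 19 rose and 1 fell between the groups (median 1.05, adjusted p = 9.44e-12), and within the high-ratio and the low-ratio arrays the medians were 0.80 and 1.13.

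Endoplasmic reticulum chaperones and secretory pathway genes rose in 21 of 27 cases, none fell and 6 did not pass (25 and 0 adjusted over the list alone), with a median of 0.84. Camera gave an adjusted p = 8.55e-15, and an adjusted p = 0.184 with an estimated correlation, and 9 of the 21 calls held without any 1 array. SSR3, part of the translocon, rose by 1.49, HYOU1, a chaperone, from 2829 ± 250 to 7759 ± 383 (1.42) and SDF2L1 by 1.22. FKBP14, a prolyl isomerase, rose by 1.69 but did not pass without control 2 (0.0503), control 3 (0.0643), TGF-β1 1 (0.0723) or TGF-β1 3 (0.0695). In the 5′/3′ split, 8 of the genes were higher and 0 lower in high-ratio arrays (median 0.16), and with the split as a block 24 rose and 0 fell between the groups (median 0.78). Ribosomal protein genes were lower by camera (median −0.13, adjusted p = 0.0154, and adjusted p = 0.534 with an estimated correlation), though 0 of 23 passed singly and 0 adjusted over the list alone, with 8 at an unadjusted limma p under 0.05, all lower. That call was lost without control 1 (0.0615) or TGF-β1 1 (0.0541). The largest differences were in RPS9 (−0.27, adjusted p = 0.0594) and RPL11 (−0.23, adjusted p = 0.102), which passed without TGF-β1 2 (0.0217 and 0.0249) and with array weights (0.00437 and 0.0079). RPS9 also passed with quantile normalization (0.0436), the dimmer 50% of probe sets left out (0.0449) and the split as a block (0.0346). RPL22 and RPL18, uncalled at their brightest probe sets, were called lower at 2 of 5 and 1 of 3 of their probe sets. The mean of RPL22's probe sets passed (−0.33, adjusted p = 0.0286).

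Of 22 WNT pathway genes, 2 rose, 4 fell and 16 did not pass (2 and 5 adjusted over the list alone, median −0.15, camera adjusted p = 0.583). The WNT antagonists DKK1 and DKK2 rose by 2.45 and 1.89, while SFRP1, another antagonist, fell from 5634 to 2176 (−1.32) at 2 of its 3 probe sets called, and the receptor FZD1 fell by 0.95 at 1 of its 2 probe sets (−0.48 for their mean, adjusted p = 0.128). FZD7 (−0.87) and TCF7L2 (−0.53) did not pass without control 3 (0.0616 and 0.0988), TGF-β1 1 (0.0503 and 0.111) or TGF-β1 3 (0.0591 and 0.119), nor TCF7L2 without control 2 (0.102). FZD7 was called at 1 of its 2 probe sets and TCF7L2 at 1 of 6 (−0.41 for their mean, adjusted p = 0.137). Growth factors and their receptors rose in 7 of 24 cases, 3 fell and 14 did not pass (8 and 4 adjusted over the list alone, median 0.28, camera adjusted p = 0.127). HGF, uncalled at its brightest probe set (−1.04, adjusted p = 0.169), was called lower at 3 of its 4 probe sets. The mean of all 4 passed (−1.68, adjusted p = 0.00205). HBEGF, an EGF receptor ligand, rose from 184.3 ± 24.5 to 2174 ± 282 (2.87) and PDGFA by 1.78 at 1 of its 2 probe sets, while PDGFD fell by 2.85, PDGFRA from 17930 ± 1570 to 6636 ± 591 (−1.42) and EGFR by 1.37 at 1 of its 5 probe sets (−0.46 for their mean, adjusted p = 0.155). BDNF, a neurotrophin, rose by 1.60 but did not pass without control 2 (0.0748), control 3 (0.0913), TGF-β1 1 (0.0979) or TGF-β1 3 (0.0964). In the IGF system, 3 of 13 genes rose, 1 fell and 9 did not pass (3 and 3 adjusted over the list alone). Camera did not call it (adjusted p = 0.817), its median (−0.23) lying below and its mean (0.52) and test above 0. IGFBP3 rose by 4.90, IGFBP7 from 1838 ± 237 to 19290 ± 3510 (3.29) and IGF1 by 1.62, and IGFBP6 (−0.44) did not pass without control 2 (0.082), control 3 (0.0804), TGF-β1 1 (0.0785) or TGF-β1 3 (0.0826).

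YAP, SRF and immediate early genes rose in 6 of 17 cases, 5 fell and 6 did not pass (6 and 6 adjusted over the list alone, median 0.25, camera adjusted p = 0.421). CCN1, a YAP target, rose by 1.98, the transcription factor SRF by 1.88 and MYC by 1.59. JUN fell from 8830 ± 59.4 to 2939 ± 680 (−1.57) at 2 of its 4 probe sets called, DUSP6 by 1.28, EGR1 by 1.00 and IER2 by 0.65, and EGR3 (−0.73) did not pass without control 1 (0.0708), control 2 (0.106), control 3 (0.0814), TGF-β1 1 (0.135) or TGF-β1 3 (0.149). Mesenchymal and lung development transcription factors fell in 11 of 23 cases, 3 rose and 9 did not pass (11 down and 3 up adjusted over the list alone). The list was lower (median −0.54, camera adjusted p = 0.00217, and adjusted p = 0.24 with an estimated correlation), and 7 of the 14 calls held without any 1 array. TCF21 fell from 2343 ± 205 to 493.7 ± 63.6 (−1.99), TWIST1 from 3824 ± 187 to 1119 ± 22.6 (−1.66), FOXF1, of the lung mesenchyme, from 7318 to 2594 (−1.44) and TBX2 by 1.33 at 2 of its 3 probe sets called. GLI2 (0.72), SNAI1 (0.71) and MEOX1 (0.61) did not pass without control 2 (0.0568, 0.155 and 0.138), control 3 (0.0989, 0.105 and 0.135) or TGF-β1 1 (0.105, 0.143 and 0.106), nor SNAI1 and MEOX1 without TGF-β1 3 (0.0563 and 0.107), nor SNAI1 without TGF-β1 2 (0.0711). GLI2 was called at 1 of its 2 probe sets (0.43 for their mean, adjusted p = 0.0606). Among 12 lipofibroblast and adipogenic genes, 2 rose, 4 fell and 6 did not pass (2 and 5 adjusted over the list alone, median −0.49, camera adjusted p = 0.0714). The list was called lower without TGF-β1 3 (0.0436) and with no filter on dim probe sets (0.0276). TCF21 and PDGFRA, also in other lists, fell as given, PLIN2, a lipid droplet protein, fell by 1.24 at 1 of its 2 probe sets (−0.43 for their mean, adjusted p = 0.331) and PPARG, the regulator of fat cell formation, by 1.15. DGAT1 (1.12) and FABP5 (0.69) did not pass without control 3 (0.0642 and 0.098), TGF-β1 1 (0.0693 and 0.0711) or TGF-β1 3 (0.0694 and 0.0608), nor FABP5 without control 2 (0.082).

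Among markers of cell types other than smooth muscle, 3 lists held a changed gene. Of 10 epithelial markers 1 rose, none fell and 9 did not pass (1 and 0 adjusted over the list alone, median 0.02, camera adjusted p = 0.437). The riser was KRT18, a keratin with many pseudogenes whose probe set is therefore of uncertain specificity, from 1392 ± 92.3 to 10870 ± 4210 (2.77, adjusted p = 0.00109). It was also the single riser among 4 mesothelial markers, where none fell and 3 did not pass (1 and 0 adjusted over the list alone, median 0.39), too few for camera. Of 7 endothelial markers none rose, 1 fell and 6 did not pass (0 and 1 adjusted over the list alone, camera adjusted p = 0.972), the median (0.06) and test pointing up and the mean (−0.08) down. TEK, an angiopoietin receptor, fell from 973.7 to 306.7 (−1.35) at 1 of its 2 probe sets. None of 10 leukocyte markers passed (0 adjusted over the list alone, 2 at an unadjusted limma p under 0.05, median 0.01, camera adjusted p = 0.802), the largest differences being in MS4A1 (−0.48, adjusted p = 0.0638) and CD3E (0.37, adjusted p = 0.121). Both passed with array weights (0.0172 and 0.0266), and MS4A1, which has 1 probe set tested, when every gene was read as the mean of its probe sets (0.0495).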

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

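No test was run on these values beyond their comparison between the groups. Among the 68 control probe sets left out of the main comparison, the 5′ and middle control probe sets of beta-actin differed between the groups, every TGF-β1 array lying above every control array. The 5′ set stood at 31870 ± 2600 in control cells and 48460 ± 3030 with TGF-β1 (log2 difference 0.604, adjusted p = 0.0133). The middle set stood at 36350 ± 636 and 51250 ± 2370 (log2 difference 0.493, adjusted p = 0.00304). The 3′ set had a log2 difference of 0.36 (adjusted p = 0.0539), and the GAPDH control probe sets differed by −0.07, −0.10 and −0.06 without passing (adjusted p 0.517, 0.52 and 0.575). The beta-actin 3′ over 5′ ratio followed the 5′/3′ split of the arrays, which was not in this fit. The high-ratio arrays were 1 control and 2 TGF-β1 arrays, and a part of the split in these differences was not tested.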

How the results depend on the processing

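The block for the 5′/3′ split and the fit without control 1 and TGF-β1 2 together were chosen after the data were seen, the other alternatives before. NOX4 kept its direction and call in every alternative, at 3.12 to 4.42 across pseudocounts and 3.78 to 3.92 with 1 array left out. No gene called both with the deposited values and in an alternative changed sign, but some called only with the deposited values did. With a pseudocount of 1 these were 1 of the 1579 such calls tested, and at the 10th percentile 1 of 1594. With the mean of a gene's probe sets they were 4 of 1604, and no other alternative had any. Leaving out 1 array gave 1007 to 3494 probe sets, 668 to 1462 with at least 2-fold change, 637 to 2124 genes, a share that rose of 42.75 to 55.42% and 12 to 18 lists. The numbers of probe sets and genes were lowest without control 2, control 3, TGF-β1 1 or TGF-β1 3, which leaves 1 of control 1 and TGF-β1 2 as 1 of 2 arrays in its group, and highest without TGF-β1 2, while that of lists was lowest without control 1 and highest without TGF-β1 3. Array weights, lowest in control 1 (0.358) and TGF-β1 2 (0.371), gave 7127 probe sets, 1738 at least 2-fold, 4154 genes and 42.87% that rose. The fit without control 1 and TGF-β1 2 together gave 6773, 2164, 3910 and 42.07%, without the 2 arrays nearest to the other group. Its controls are all low-ratio and its TGF-β1 arrays all high-ratio, so its counts and the calls it adds or ends below hold the differences of the split as well as those of the treatment, and are no treatment result alone. With the 5′/3′ split as a block 4323 probe sets and 2648 genes were called. Equally numbered arrays deviated from their group means with r = 0.471, 0.559 and −0.229 across probe sets and control 1 correlated better with TGF-β1 3 (0.488) than with its own number, so the arrays were treated as sharing only a number, a hint from the data and not the design. The replicate number as a block gave 3732 probe sets, 2224 genes, 17 lists and a share of 43.84%, with CCN2 (0.0078) and PTGS1 (0.0124) passing, and the cause was not tested, nor for the array weights or the split. A pseudocount of 412 gave 613 probe sets with at least 2-fold change, by construction since it shrinks every difference. With an estimated correlation 0 lists were called, against 15, and the cause was not tested. The median log2 differences of these 15 lists, which that setting cannot move, were 0.64 for TGF-β response, 0.54 for BMP and ID, 0.82 for contractile, 0.28 for collagen, 0.89 for collagen processing, 0.20 for non-collagen matrix, −0.34 for interferon, −0.44 for CDK inhibitor, 0.15 for glycolysis, 0.65 for cholesterol, 1.24 for amino acid, 0.84 for chaperone, −0.54 for transcription factor, −0.13 for ribosomal and 0.99 for smooth muscle genes. Calls of lists that other settings ended or added, with their medians and causes not tested, were as follows. Non-collagen matrix lost its call with a pseudocount of 1 (0.15), the dimmer 50% left out (0.20, fewer genes tested) and the split as a block (0.051), interferon genes with the dimmer 50% left out (−0.32), and glycolysis with array weights (0.19) and without the 2 arrays (0.15). Antioxidant genes gained a call with quantile normalization (−0.52), array weights (−0.60), the replicate block (−0.51), the mean of probe sets (−0.49), the split (−0.43) and without the 2 arrays (−0.68). Oxidative phosphorylation gained one with no filter (−0.26), array weights (−0.28) and without the 2 arrays (−0.29), and lipofibroblast genes with no filter (−0.46). Integrins gained one with the dimmer 50% left out (0.90), the split (0.35) and without the 2 arrays (0.53), growth factors without the 2 arrays (0.29), and cell cycle genes with the replicate block (−0.30), the mean of probe sets (−0.23) and the split (−0.41). With 1 array left out the medians of lists whose call changed ran from 0.38 to 0.63 for BMP and ID, 0.41 to 0.51 for integrins, −0.65 to −0.41 for antioxidant, −0.41 to −0.0077 for cell cycle, 0.14 to 0.22 for glycolysis, −0.28 to −0.17 for oxidative phosphorylation, −0.66 to −0.37 for lipofibroblast and −0.17 to −0.089 for ribosomal genes. Of the other values of these results, 72 showed no such change, a label that allows wide differences, as 3732 probe sets with the replicate block had it against 2507. Over all alternatives, named genes held in 2273 comparisons, lost their call in 98 and gained it in 28, and lists held in 617, lost it in 25 and gained it in 27. Those that held include genes and lists uncalled both ways, and settings such as centring on array medians that left the counts unchanged. These tallies therefore overstate how far the calls hold. Named genes tested numbered 113 with a pseudocount of 1 and 110 with the dimmer 50% left out. In 20 of the 617, over 7 lists uncalled both ways, camera's direction turned (lowest adjusted p 0.445), among them the cell cycle list. Signal over background limits genes with levels near 131 or below, whose folds are understated.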

Other observations

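The genes and families in the next paragraph, the tests of mixed RNA and of growth, and both tests on the amino acid genes were chosen after the results were seen. Of these genes COL4A1, COL4A2 and PDLIM7 also belong to the lists fixed before. The predictions for the splits of the arrays and for 5′ signal loss were written before the results of those tests. The 5′/3′ split that the latter test concerns was defined from the array values, not fixed with the comparison.

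Outside the lists, CILP, a cartilage matrix protein, rose from 639.7 ± 33.8 to 8239 ± 2860 (log2 difference 3.37), TFPI2, a protease inhibitor, by 3.24, NNMT, which methylates nicotinamide, by 3.16, AMIGO2, an adhesion protein, by 3.14, ACTC1, cardiac α-actin, by 3.09, PRG4, lubricin, by 2.91 and LMCD1 by 2.89. PLPP3, a lipid phosphatase, fell by 2.61, ZFP36L2, an RNA-binding protein, from 6644 ± 391 to 994.3 ± 132, EPAS1, a hypoxia-inducible factor, from 13630 ± 3270 to 2289 ± 912 (−2.54), PHLDA1 by 2.44 and TXNIP, an inhibitor of thioredoxin, by 2.35. PSMB8, an immunoproteasome subunit, had a difference of −2.55 that did not pass without TGF-β1 1 (0.0501). The 4 type IV collagen genes named here went both ways, COL4A1 (2.14) and COL4A2 (1.38) rising and COL4A5 falling by 2.51, while COL4A6 (−2.12, adjusted p = 0.0192, at 1 of its 2 probe sets) did not pass without control 2 (0.0669), control 3 (0.0825), TGF-β1 1 (0.0859) or TGF-β1 3 (0.0769). Of 333 families screened, 3 were called, among them the PDLIM family, which links actin to signalling proteins (5 of 6 rose, 1 fell, median 1.14, adjusted p = 0.0289, and unadjusted p = 0.0201 with an estimated correlation). PDLIM5 rose by 1.98 at 5 of its 6 probe sets, PDLIM4 by 1.40 at 3 of 4 and PDLIM7 by 1.14, while PDLIM1 (−0.78) did not pass without control 2 (0.135), control 3 (0.144), TGF-β1 1 (0.153) or TGF-β1 3 (0.152). PDLIM3 (1.13) and PDLIM2 (0.62) did not pass without control 3 (0.0568 and 0.112), TGF-β1 1 (0.0929 and 0.0863) or TGF-β1 3 (0.0892 and 0.0993), nor PDLIM2 without control 1 (0.0536), control 2 (0.0547) or TGF-β1 2 (0.0648). The aldo-keto reductases fell in 5 of 5 cases (median −0.83, adjusted p = 0.0194, and unadjusted p = 0.0696 with an estimated correlation), among them AKR7A2 by 0.83 and AKR1C1 by 0.94. AKR1C1 is so close to AKR1C2 (−1.04) that their probe sets cannot be relied on to tell them apart. AKR1C2, AKR7A3 (−0.65) and AKR1B10 (−0.78) did not pass without control 2 (0.0511, 0.114 and 0.0728), control 3 (0.0657, 0.0732 and 0.0842) or TGF-β1 1 (0.0626, 0.104 and 0.0681), nor AKR7A3 and AKR1B10 without TGF-β1 3 (0.123 and 0.0768).

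The real grouping called 2507 probe sets, and the 10 splits of 6 arrays are too few for a share under 0.05. As many were called by 1 of the 10, the real one, and the highest other was 365, in the split by the 5′/3′ ratio. With that split as a block the groups differed at 4323 probe sets.

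The arrays with high and low 5′/3′ ratios of the long control transcript differed at 2944 probe sets beside the treatment. Mixing of the groups' RNA in control 1 and TGF-β1 2 would move risen and fallen genes alike, if signals were proportional to the amount of RNA. The 100 risen and 100 fallen genes were chosen on the other arrays, where the split and the treatment coincide. Control 1 lay 8.04% of the way to the other group for risen and 55.9% for fallen genes (difference −47.8 percentage points, 95% interval −57.1 to −36.2). TGF-β1 2 lay 53.9% and 17.1% of the way (36.8, 26.9 to 43.4). Under that assumption the shares argue against mixing as the whole cause. Since a step that the notes do not name shaped the deposited values, the assumption could not be checked. Loss of 5′ signal may account for part of the split, since pairs of probe sets of 1 gene correlated less for the split (r = 0.502) than for the treatment (r = 0.906) across 1488 genes, by −0.404 (95% interval −0.466 to −0.343), though a split effect that is small beside the noise would lower r too, and while the 3′ over 5′ ratios of the GAPDH and beta-actin controls were higher in every low-ratio array than in any high-ratio array, as 5′ loss would have it, they spanned only 0.830 to 0.982 and 0.856 to 1.24. Different growth of the cultures also stays open, as the cell cycle list differed by the split (camera unadjusted p = 1e-10, and unadjusted p = 0.0391 with an estimated correlation). The cell cycle list did not stand alone in this. With an estimated correlation camera's unadjusted p for the split was lower in the amino acid (0.0161), non-collagen matrix (0.0257) and collagen processing (0.0349) lists. Loss of 5′ signal and different growth could apply together, and nothing here separates them.

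The rise of the amino acid synthesis and ATF4 genes followed the treatment and, in part, the 5′/3′ split. With the split as a block its median was 1.05 against 1.24 without, which argues against the split as the whole cause. The cytosolic aminoacyl-tRNA synthetases, genes outside the list, rose in 9 of 15 cases and fell in none (median 0.66, camera p = 6.57e-07, adjusted p = 0.000219 over the 333 families, and unadjusted p = 0.0491 with an estimated correlation), but as a set chosen after the results were seen they do not decide whether the list holds chance members. Among them GARS1 rose by 1.42 and TARS1 by 1.16, while KARS1 (−0.08) and LARS1 (−0.02) did not pass. Chance members of the list and a treatment effect on amino acid supply both stay open, the latter untested.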
